A study of Mus musculus with 4 samples.

How the data were processed

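Gene expression was measured with 4 Affymetrix Mouse Genome 430 2.0 arrays, which carry short oligonucleotide probe sets and are read in 1 colour. Each array held RNA from a pool of 3 mammary tumors taken from 3 different female C57BL/6 mice that carried the polyoma virus middle T oncogene, a transgene that drives mammary tumors. Per the labels, 2 pools came from mice null for St6gal1 and 2 from wild-type littermates, at an age of 110 days and 14 days after tumor onset. Per the labels' protocols, 100 mg of tissue was homogenized, total RNA was extracted with Ultraspec, and 6 ug of total RNA was turned into biotinylated cRNA.

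The deposited values were linear probe set intensities. Per the submitters' processing notes they were made with MAS5, whose version is not given in the sources used here. MAS5 summarises the probes of a set into 1 signal and scales each array to a common mean, and the deposited intensities of all 4 arrays had the same mean, 2500.01, after trimming 2% at each end. They were therefore used as deposited. Detection calls were not used here. Of 45101 probe sets, 64 control probe sets were left out, which left 45037. The probe annotation gave 1 gene symbol for 34945 of these, several for 932 and none for 9160. Of the probe sets with 1 symbol, 34741 matched a gene of the mouse reference table (assembly GRCm38.p6), which updated 0 symbols. The files name no genome build, so that table was used only for names and for which genes neighbour each other. Each column was mapped to 1 sample, and 0 columns of values stayed unmapped. No probe set with several symbols or none was named.

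Intensities were turned into log2(value + 44), where 44 is the 10th percentile of all values. A fold change on this scale understates the change of dim genes. Probe sets with a mean at or above the median were tested, which kept 22519. The fit was limma's lmFit and eBayes with an intensity trend, with set and genotype as terms, and Benjamini-Hochberg adjustment over all probe sets tested, with a threshold of 0.05. The set is a block because the series' design text compares 1 null with 1 wild-type pool in a first set and another such pair in a second set. Deviations from the group means correlated at 0.612 within each set, a value that is the same for both sets by construction. The fit leaves 1 residual degree of freedom, to which eBayes added 13.5 prior degrees of freedom. Standard errors are those of limma.

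Gene lists were tested with camera at the preset correlation 0.01, 1 probe set per gene (the brightest), for lists with at least 5 members tested, with camera at an estimated correlation and fry beside it. Camera at an estimated correlation and fry rest on the 1 residual degree of freedom of the fit, so they have little power to call a list. Of the lists, 28 could be tested. The Y-linked list had 0 members above the filter and the erythrocyte list had 2, so neither was tested. The design, the lists, the rule for naming genes and the alternatives, except each set alone for the list medians, were chosen before the data were examined. The rule named St6gal1, up to 12 genes higher and 12 genes lower in the null pools, ranked by the smaller of the log2 ratios of the 2 sets among those past the threshold, and up to 4 members per list with the largest changes that went the same way in both sets. Genes named outside this rule were chosen after their values were seen: further members of the lists that passed the threshold, the members of the lists in the closing section, and genes named as neighbours there. Unnamed and immunoglobulin probe sets were skipped in naming.

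The fit was tested on simulated arrays, in 5 runs of 22519 probe sets of which 200 were changed. The means were the real ones, the set effects and the spread with its intensity trend were taken from this fit, and probe sets varied independently. The fit recovered 48.1% of the probe sets changed 1.5-fold, 77.6% of those changed 2-fold and 96.4% of those changed 3-fold. Of all its calls, 17.9% were unchanged probe sets, from 4.2% to 26.8% in single runs, more than the threshold of 0.05 allows. The same data fitted without the set, or without the intensity trend, recovered 0% at each size. Data built with both terms favour the fit that holds them, so this does not judge the other fits. In 200 simulated lists of 20 unchanged genes, 4% reached p under 0.05 with camera, as did 100% of 100 lists of 20 genes raised 1.5-fold. Of 1000 random lists of 20 tested genes in the real data, 2.3% did. Genes drawn at random or simulated independently do not move together as markers of 1 cell type can. These checks therefore do not calibrate the preset correlation for the marker lists.

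With 4 arrays, an exact permutation of 2 against 2 arrays cannot give a two-sided p below 0.333, so no such test could pass the threshold. The number of arrays limits the precision of every value. Alternatives were quantile and cyclic loess normalization, other filters and pseudocounts, no set term, no intensity trend, a robust trend, each array left out, each set alone, other list tests, other fold thresholds and other windows. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.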

Results

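The 4 arrays compared mammary tumors of St6gal1-null mice with those of wild-type littermates, 2 pools of 3 tumors per genotype. St6gal1 encodes the enzyme that adds sialic acid in an alpha2-6 linkage to N-glycans. The question was which transcripts differ in tumors that form without it. Median intensities were 588 and 591 on the null arrays and 619 and 593 on the wild-type arrays. The 3'/5' signal ratio of Gapdh, which rises as RNA is degraded or labelled less completely, was 0.873 in the null and 0.869 in the wild-type pool of set 1. In set 2 it was 2.13 in the null and 1.57 in the wild-type pool. The same ratio for beta-actin was 1.53 in the null and 1.63 in the wild-type pool of set 1. For set 2 the beta-actin ratio was 2.12 in the null and 1.96 in the wild-type pool, a smaller difference than for Gapdh. In set 1 the control probe sets for 18S ribosomal RNA read lower in the null pool, 4272 against 11503 at the 5' and 2600 against 4222 at the 3' end. In set 2 the 3' signals were 835 and 910, and the 5' signals, 217 and 486, lay within the unspecific level (up to 565 for Y-linked probe sets in these female animals). The set itself moved 5295 probe sets past the threshold, so each null pool was compared with the wild-type pool of its own set.

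St6gal1, the targeted gene, was measured first. The brighter of its 2 probe sets read 2337 in the null and 2330 in the wild-type pool of set 1, and 3642 in the null and 2796 in the wild-type pool of set 2. Its log2 ratio was 0.19 ± 0.16 (SE, n = 2 pools per genotype), with a limma adjusted p of 0.563. The dimmer probe set lay below the filter and was not tested, and read 492, 486, 475 and 548 in null 1, wild type 1, null 2 and wild type 2. It lies within the unspecific level and could not show a loss. The brighter probe set showed no loss in the arrays labelled null. The part of the gene that the null allele lacks is not given in the sources used here, and a probe set outside it checks nothing, so the directions below rest on the labels.

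The genes that were highest in the null pools in both sets included several secreted and matrix proteins. Where both arrays of the dimmer genotype read at or below 565, the unspecific level, the fold is given as a bound against that level. This step was chosen after seeing the data, and the rank of such genes rests on values not told from that level. The bound takes the mean log2 signal of the 2 brighter arrays and leaves out their spread. Each "at least" is therefore an estimate over both sets, and the fold against that level can be lower in a single set. Mup5, a major urinary protein, rose 6.17-fold (log2 2.62 ± 0.18, adjusted p = 3.08e-07). Lum, encoding the collagen-binding proteoglycan lumican, rose 4.31-fold (log2 2.11 ± 0.12). Mmp23 rose at least 2.86-fold, Pdgfd at least 2.72-fold and Tnxb 4.46-fold, encoding a metalloprotease, a platelet-derived growth factor and a tenascin. Dio2, which activates thyroid hormone, rose at least 3.62-fold, and Rarres2, which encodes the chemoattractant chemerin, rose 5.22-fold. Aoc1 and Ndn rose at least 2.77-fold and at least 3.41-fold, and Pcp4, Efemp1 and Thbs4 rose 4.26-fold, 3.96-fold and 3.87-fold. For Tnxb and Rarres2 only 1 of the 2 wild-type arrays read above the unspecific level, so their folds rest in part on values not told from it. Each of these 12 genes passed the threshold and was higher in both sets. The second tested probe set of Mmp23 had a log2 ratio of 0.96.

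The genes that were lower in the null pools included Duoxa1, a maturation factor of dual oxidase, which was at least 8.49-fold lower (adjusted p = 3.36e-07). Its signal was 548 against 5280 in set 1 and 235 against 4972 in set 2. Tmem87a was at least 5.83-fold lower, and Rbm45 fell by 2.81 on the log2 scale. Defb1, an antimicrobial defensin, was at least 3.08-fold lower, and S100a8, a calcium-binding protein abundant in neutrophils, fell by 1.86. Wif1, a secreted Wnt inhibitor, fell by 1.81, and Htr4, a serotonin receptor, was at least 2.90-fold lower. For a further 5 genes the probe set that led did not speak for the whole gene. The leading probe set of Deptor, an inhibitor of mTOR, fell by 2.47, while its 4 other tested probe sets ranged from -1.08 to 0.13. Those of Marchf6 and Paxip1 were at least 2.62-fold and at least 2.84-fold lower and that of Sdc2 fell by 2.18, with other probe sets at -0.16, from -0.04 to 0.05, and from -0.61 to -0.09. Elf5, a transcription factor of the secretory mammary lineage, fell by 1.96 on its leading probe set, while its brighter probe set had a log2 ratio of -0.12.

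Over all 22519 probe sets tested, limma called 1658 past adjusted p 0.05, 921 higher and 737 lower in the null pools, and 405 of them changed at least 2-fold. They belonged to 1235 genes, of which 7 had calls in both directions. At least 2-fold changes in both sets and in the same direction were seen for 250 probe sets, 179 higher and 71 lower, against 8 in opposite directions. Of the 250, 248 were called. The log2 ratios of the sets correlated across probe sets at a Pearson r of 0.445 and a Spearman rho of 0.369, and genes are not independent replicates. In set 1 alone, 367 probe sets were at least 2-fold higher and 243 lower, and in set 2 alone 414 and 423. Without the set term limma called 0 probe sets (1261 at an unadjusted p under 0.05, and between 5 and 26 called with 1 array left out as well), and without the intensity trend 0 (3512 at an unadjusted p under 0.05). In simulated data 17.9% of limma's calls with both terms were unchanged probe sets. Those data held independent probe sets and a chosen number of changed ones, so this share cannot be carried over to the 1658 calls. The share of unchanged probe sets among the 1658 was not estimated and may be higher or lower.

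**Figure D1:**
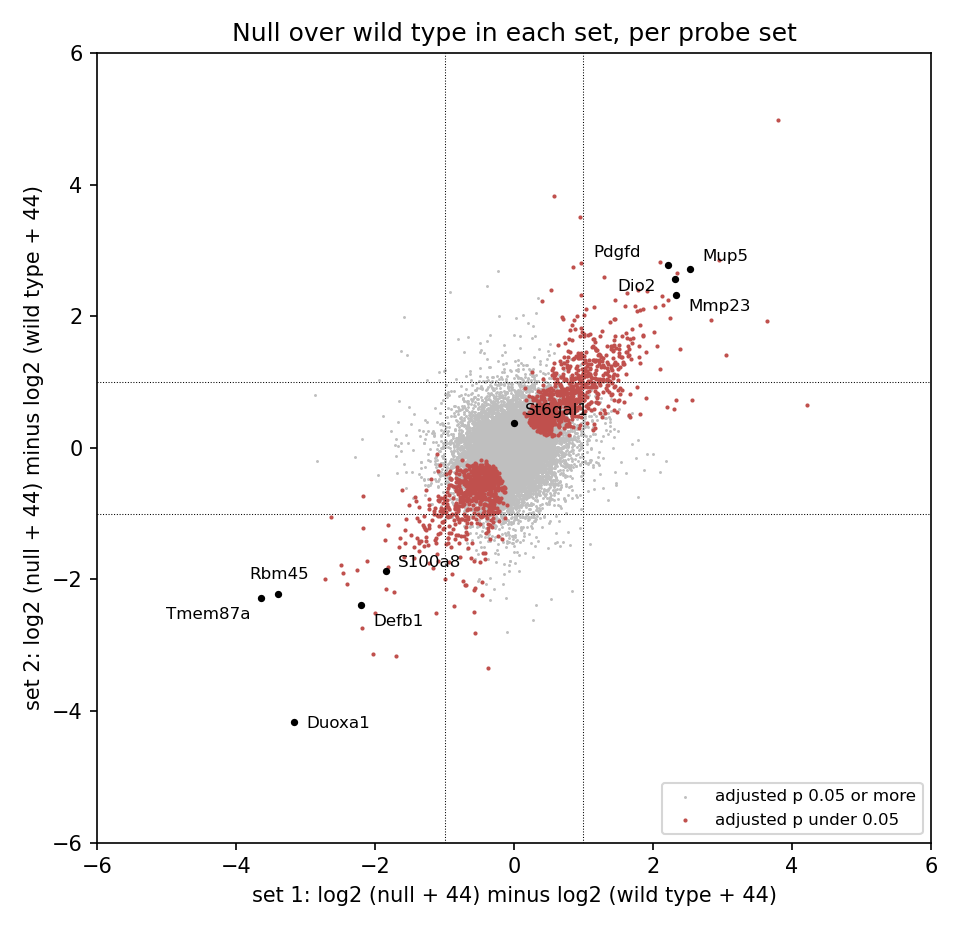
Log2 ratio of null over wild type in set 1 (x axis) and set 2 (y axis) for each of the 22519 tested probe sets, on the log2(value + 44) scale. Red points passed adjusted p 0.05, grey points did not, dotted lines mark 2-fold and black points are named genes. Duoxa1 is plotted lowest of the named genes, at -3.67 on average with null signals within the unspecific level, and St6gal1 lies near 0, at 0.19.

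Markers of fibroblasts and the fibrillar matrix rose together. Of 23 members tested, 21 rose and 0 fell (22 rose adjusted over the list alone), with a median log2 of 1.11, or 2.16-fold (camera adjusted p = 8.77e-38). With an estimated correlation the adjusted p was 0.534. Col1a1 and Col1a2, the chains of type I collagen, rose 3.57-fold and 2.91-fold, and Dpt, encoding dermatopontin, rose 3.02-fold. The second tested probe set of Col1a1 had a log2 ratio of only 0.48, and that of Col1a2 had 1.54. The median was 1.14 in set 1, where the Gapdh ratios were nearly equal, and 1.19 in set 2. The 18S signal was lower in the null pool of set 1, while in set 2 the 3' signals were 835 and 910.

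Most adipocyte markers rose as well, as did a minority of the muscle and vessel markers. Of 9 adipocyte markers 7 rose and 0 fell (8 rose adjusted over the list alone), with a median of 1.23 (adjusted p = 1.1e-12, and adjusted p = 0.534 with an estimated correlation). Adipoq, the adipocyte hormone adiponectin, rose 3.08-fold, and Plin4 and Retn rose 2.81-fold and 2.65-fold. Of 13 skeletal muscle markers 3 rose and 0 fell (7 rose adjusted over the list alone), with a median of 0.72 (adjusted p = 5.22e-04, and adjusted p = 0.534 with an estimated correlation). They were Ckm, at least 1.91-fold, and Tnni2 and Tnnc2, at 2.52-fold and 1.83-fold, where Tnni2 read above the unspecific level on 1 of the 2 wild-type arrays (880 and 236). Of 18 markers of endothelium and pericytes 4 rose and 0 fell (8 rose adjusted over the list alone), with a median of 0.57 (adjusted p = 7.36e-05, and adjusted p = 0.534 with an estimated correlation). Rgs5, a pericyte marker, rose 1.84-fold and Vwf, von Willebrand factor, rose 1.72-fold. In set 1 alone the medians of the adipocyte, muscle and endothelial lists were 1.38, 0.71 and 0.59, and in set 2 alone 1.12, 0.64 and 0.33.

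Genes of matrix remodelling went different ways. In the mesenchymal transition list 6 of 18 members rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.26 (adjusted p = 2.17e-04, and adjusted p = 0.534 with an estimated correlation). Mmp3, stromelysin, rose 3.36-fold, fibronectin (Fn1) 3.13-fold and tenascin C (Tnc) 2.98-fold, and Cdh11, Twist1 and S100a4 also rose. Cdh2, which encodes N-cadherin, fell by 0.73 and Tgfb3 fell by 0.47. Fibroblasts are known to make several of these proteins. In the basement membrane list 6 of 17 members rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.0137, and adjusted p = 0.574 with an estimated correlation). Lama2 and Nid1 rose 2.55-fold and 2.36-fold, whereas Agrn and Col4a5 fell by 0.37 and 0.30. Among 16 metalloproteases and inhibitors, Plat, Timp1, Adamts5 and Mmp14 rose while Timp2 and Timp3 fell by 0.53 each (7 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.153).

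Among epithelial genes, basal and myoepithelial markers were lower: of 16 tested, 0 rose and 6 fell (9 fell adjusted over the list alone), with a median of -0.40 (adjusted p = 1.05e-05, and adjusted p = 0.534 with an estimated correlation). Mylk and Myh11, of the contractile apparatus, fell by 0.88 and 0.78, the oxytocin receptor gene Oxtr fell by 0.85, and Lama3, Lamb3 and Krt5 fell by 0.74, 0.56 and 0.53. In the luminal list 6 of 27 members rose and 0 fell (10 and 5 adjusted over the list alone), and the list did not pass (median 0.04, adjusted p = 0.131). Prom1 rose 2.28-fold, Pgr, the progesterone receptor gene, 1.64-fold, and Spdef and Cldn4 1.58-fold and 1.45-fold. Of 19 milk and lactogenic genes 3 rose and 3 fell (4 and 6 adjusted over the list alone, adjusted p = 0.593 for the list). Wap, whey acidic protein, fell by 1.10 and Btn1a1 by 0.61, while Lpl rose 2.48-fold and Lalba 1.36-fold.

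Genes of the dividing cell were higher. Of 36 cell cycle genes 15 rose and 0 fell (25 rose adjusted over the list alone), and 34 were higher in both sets. The median was 0.52, or 1.44-fold (adjusted p = 1.02e-14, and adjusted p = 0.534 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose 1.75-fold, Mki67 1.73-fold and Top2a 1.67-fold. Lipid and sterol synthesis genes had a median of 0.28 (11 of 25 rose and 0 fell, 14 and 2 adjusted over the list alone, adjusted p = 5.39e-06, and adjusted p = 0.593 with an estimated correlation). Adipocyte markers rose too, 7 of 9 with a median of 1.23, and Fasn, Scd1, Acaca and Elovl6 of the lipid list are known to be abundant in fat as well. Idi1 and Cyp51 of the cholesterol pathway rose 2.00-fold and 1.85-fold. The unfolded protein response had a median of 0.27 (10 of 23 rose and 0 fell, 12 and 0 adjusted over the list alone, adjusted p = 5.39e-06, and adjusted p = 0.534 with an estimated correlation), with the chaperone gene Hspa5 up 1.44-fold and Creld2 1.54-fold.

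In the list of ErbB, Wnt and Notch signalling 1 of 26 members rose and 6 fell (1 and 11 adjusted over the list alone), with a median of -0.28 (adjusted p = 0.00338, and adjusted p = 0.534 with an estimated correlation). The secreted Wnt inhibitors Wif1, Sfrp1 and Sfrp2 fell by 1.81, 0.71 and 0.58, and Notch1, Notch3 and the Notch target Hey1 fell by 0.31, 0.33 and 0.35. Hbegf, an ErbB ligand, rose 2.17-fold. The list holds inhibitors as well as activators of these pathways.

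The glycosylation and adhesion lists nearest to the targeted enzyme did not pass. Of 14 sialyltransferases 0 passed (0 adjusted over the list alone, median 0.06, adjusted p = 0.654), with St3gal6 at 0.51 ± 0.31 and St6galnac4 at 0.46 ± 0.15. St3gal4 was at -0.45 ± 0.33 and read within the unspecific level on both null arrays, so no difference was shown for it. For St3gal6 only 1 of the 2 wild-type arrays read above that level, so its value rests in part on a signal not told from it. Gne, which starts sialic acid synthesis, rose 1.39-fold, the only one of 13 members of its list (1 adjusted over the list alone, adjusted p = 0.689 for the list). Man1a, which trims mannose from N-glycans, rose 2.31-fold, the only one of 21 N-glycan genes (1 up and 3 down adjusted over the list alone, adjusted p = 0.78 for the list, median -0.04 and mean 0.03). Of 10 lectins Lgals7 alone rose, 1.33-fold (2 adjusted over the list alone, adjusted p = 0.675 for the list). Of 19 integrins Itga8 alone fell, by 0.47 (1 adjusted over the list alone, adjusted p = 0.492 for the list), and of 29 focal adhesion genes 0 passed (0 adjusted over the list alone, median 0.02, adjusted p = 0.978), with Ptk2b at -0.35 ± 0.17 and Tln2 at -0.31 ± 0.11.

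Leukocyte lists did not pass either. Of 24 macrophage and dendritic markers 4 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.09, adjusted p = 0.131), with Mrc1, the mannose receptor, up 2.04-fold and Cd163 1.82-fold, and Cd14 down, by 0.44. Among 5 markers of neutrophils and mast cells S100a8 fell by 1.86 and Cma1, mast cell chymase, rose 2.18-fold (1 up and 2 down adjusted over the list alone, adjusted p = 0.0749 for the list). Of 8 T and NK cell markers 1 rose, Thy1, which the fibroblast list also holds (2 adjusted over the list alone, adjusted p = 0.0695 for the list). Of 6 B and plasma cell markers 2 rose, Ebf1 and Ighm, and 2 fell, Jchain and Sdc1 (2 and 2 adjusted over the list alone, adjusted p = 0.684 for the list). The lists of hypoxia (3 of 26 rose, 4 adjusted over the list alone, adjusted p = 0.554), interferon response (1 of 26 rose, 5 up and 1 down adjusted over the list alone, adjusted p = 0.131), and nerve and skin (0 of 6 passed, 1 down adjusted over the list alone, adjusted p = 0.568) did not pass. Among 22 immediate early genes Klf4 and Atf3 rose 2.02-fold and 1.57-fold, and Ccn2 and Hspa1a fell by 1.07 and 0.64 (3 and 5 adjusted over the list alone, adjusted p = 0.217 for the list). The 13 Y-linked probe sets, which mark an unspecific level in female animals, read at most 565.

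Of the 28 lists, camera with the preset correlation called 11, 9 higher and 2 lower. With an estimated correlation it called 0 (0 at an unadjusted p under 0.05), and fry, which asks whether a list moves one way on balance, called 0 with a lowest adjusted p of 0.0536 (12 at an unadjusted p under 0.05). Both tests rest on the 1 residual degree of freedom of the fit and have little power. With an estimated correlation the lowest unadjusted p of camera was 0.0637, for the fibroblast list. The 0 calls therefore cannot tell whether a list moved.

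**Figure D2:**
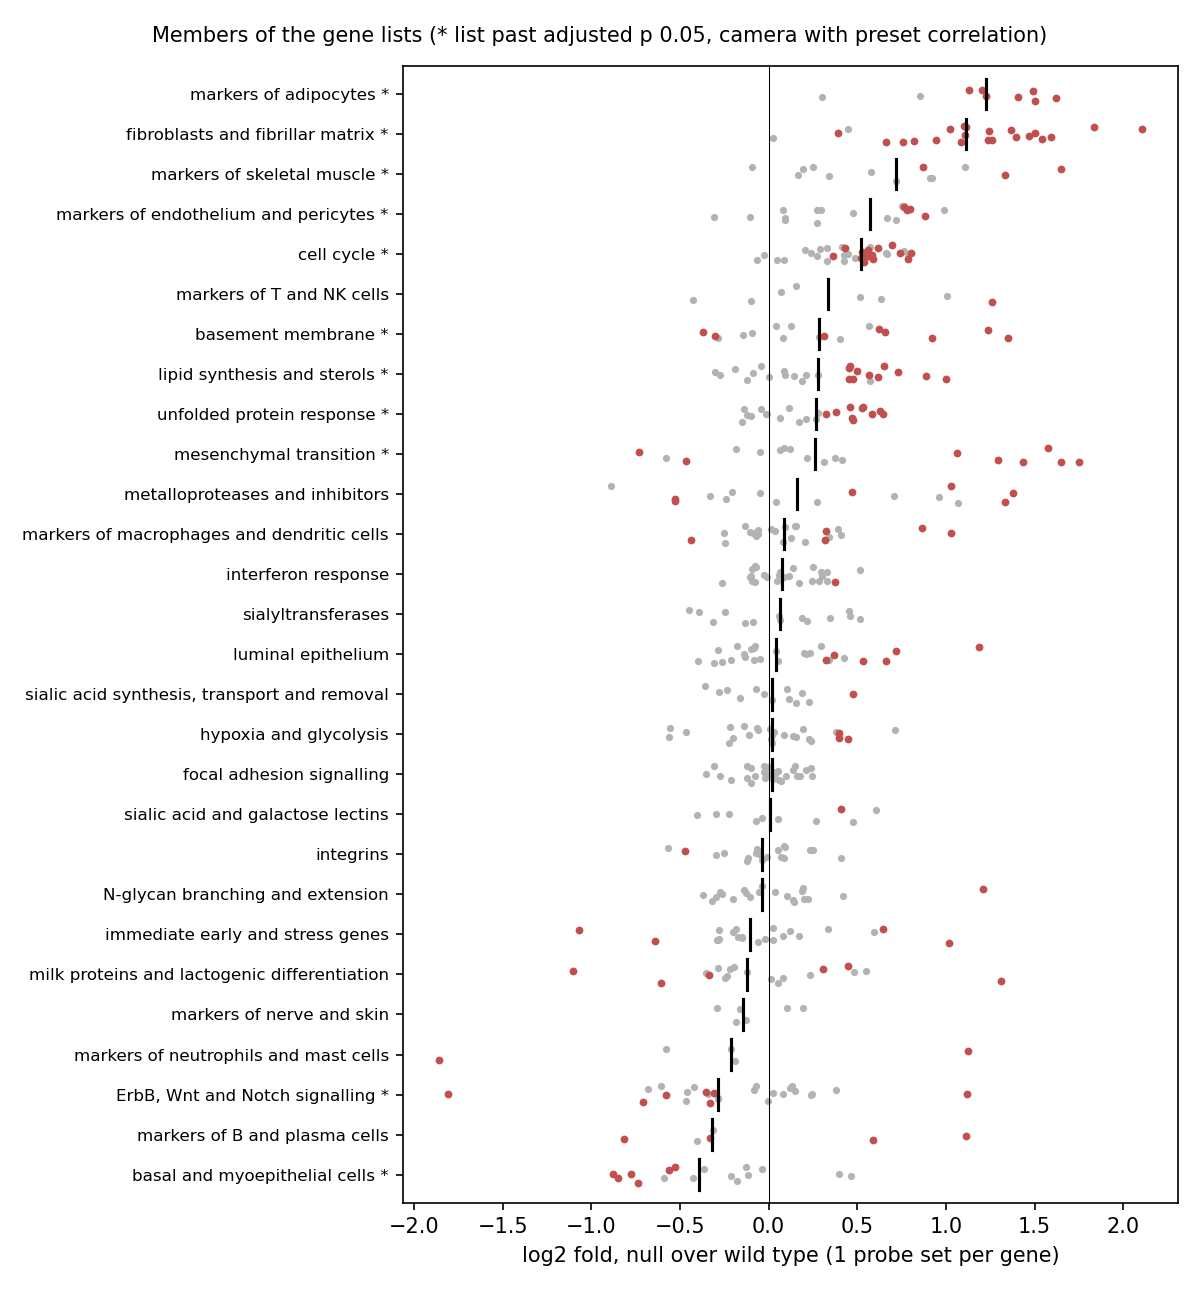
Log2 fold of null over wild type for each tested member of the 28 gene lists (x axis), 1 point per gene. Red points passed adjusted p 0.05, grey points did not, black bars are list medians and asterisks mark lists past adjusted p 0.05 with camera at the preset correlation. Fibroblast and adipocyte lists lie farthest to the right, with medians of 1.11 and 1.23, and the basal list lies farthest to the left, at -0.40.

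**Figure D3:**
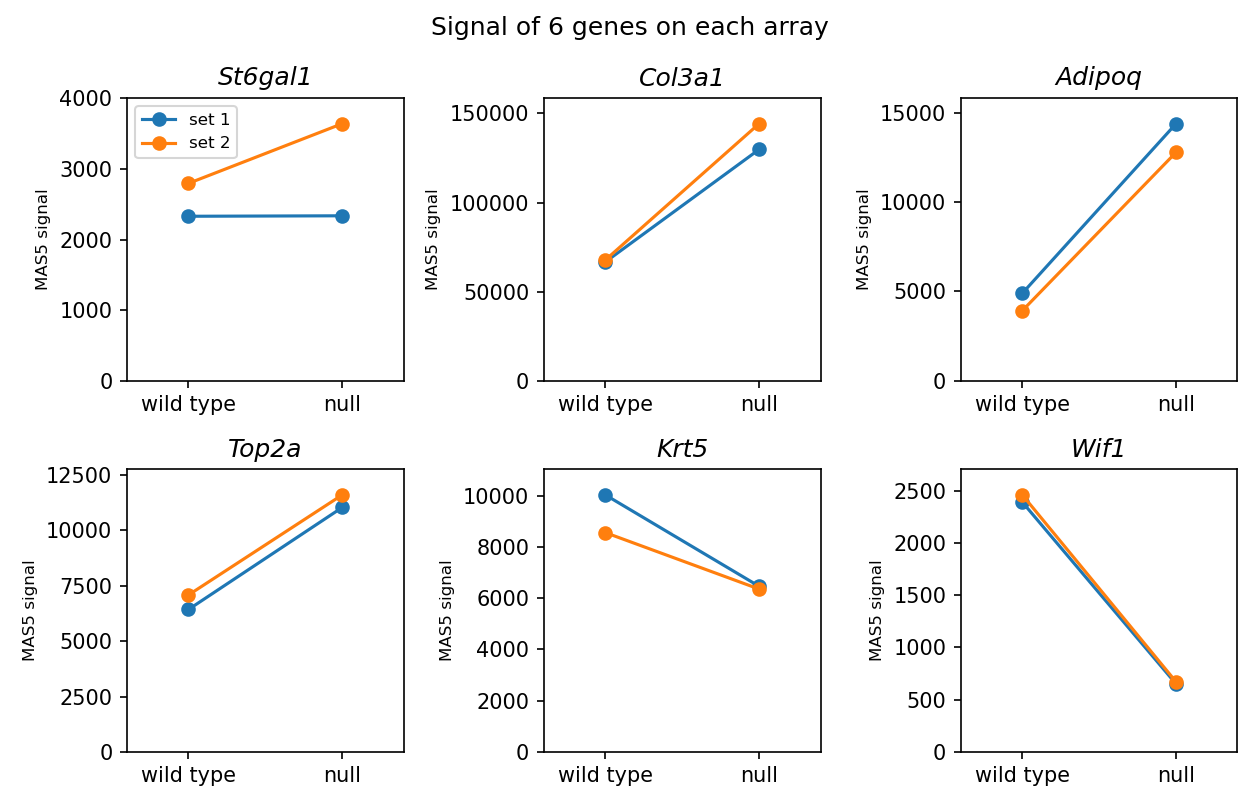
MAS5 signal (y axis, linear from 0) of 6 genes in the wild-type and null pool of set 1 (blue) and set 2 (orange), 1 point per array with a line joining the arrays of a set. Adipoq, Col3a1 and Top2a were higher and Krt5 and Wif1 lower in the null pool of both sets, and St6gal1 read 2337 and 2330 in set 1.

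Genes that neighbour St6gal1 were compared with the rest of the genome, since a null allele can carry linked sequence. Within 10 Mb, 3 of 142 tested genes (2.11%) changed at least 2-fold the same way in both sets: Adipoq, Lrrc15 and Mb21d2. On the other chromosomes 151 of 11102 did (1.36%), a difference that did not pass (Fisher's exact test, two-sided, p = 0.448). The median log2 ratio was -0.01 in both groups of genes.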

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

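Each set alone was chosen as an alternative for the list medians after seeing the data, because of the Gapdh ratios of set 2. The count of called probe sets stood or fell with 2 choices: it was 1658, but 0 with no replicate block and 0 with no intensity trend. With each array left out and no replicate block it ranged from 5 to 26, with 1 pool left to stand for its genotype and assumed to vary like the others. The 6 scaling, filter and pseudocount settings and the robust trend gave between 1351 and 1731. Without the block or the trend, simulated 3-fold changes were missed too. Those data were built from the main fit and favour it, so they do not account for the 0 calls. Same-direction 2-fold changes numbered 1583 with no filter (1119 in opposite directions), 105 with the 75th percentile filter, 925 at 1.5-fold and 52 at 3-fold, where fewer or more probe sets enter by construction. The correlation of the sets was 0.105 with no filter and 0.65 with the 75th percentile filter. The count of lists was 0 with an estimated correlation and 0 with fry, and 8 to 15 elsewhere. Camera at an estimated correlation and fry rest on the 1 residual degree of freedom of the fit and have little power. Causes beyond that were not tested. With each array left out and no replicate block, the fits do not pair the pools. Of the 1658 called probe sets, 1580 kept their direction without null replicate 2 and 1630 without wild-type replicate 1. Without wild-type replicate 2 it was 1649, and without null replicate 1 it was 1652. Single genes were checked only where they were list members or changed 2-fold the same way in both sets, and 4 of those that passed turned. Lgals7 ranged from -0.63 to 1.45 (below 0 without null replicate 1 or wild-type replicate 2). Folr1 ranged from -0.048 to 0.66 and Agrn from -0.84 to 0.10 (turned without wild-type replicate 2). Lalba ranged from -0.17 to 1.07 (below 0 without wild-type replicate 1 or null replicate 2). No other gene named here that passed the threshold, and no median of the 11 planned lists called above, changed direction under any alternative run. Some of these alternatives could not turn a called gene. With all 4 arrays, no replicate block, no intensity trend and the robust trend leave each log2 ratio as it is. All 1658 called probe sets moved the same way in both sets, so neither set alone could turn one. The medians of the lists in the next part were not run under the alternatives. A set term cannot be dropped from counts and correlations made within sets, so those were not run. Dim signals limit the rest: probe sets below the median were not tested.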

Other observations

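Except for the correlation of the 2 sets, which was planned, the tests in this part were chosen after the results above had been seen. A further set of gene lists was written then. A list of complement and coagulation genes was higher: 7 of 15 rose and 0 fell, with a median log2 of 0.66 (camera adjusted p = 8.82e-07, and adjusted p = 0.387 with an estimated correlation). Serping1, the C1 inhibitor gene, rose by 1.66 and Cfp, encoding properdin, by 1.16, and 4 of the 7 that rose are complement genes. The others were F3, which starts coagulation, F13a1, which stabilises clots, and Thbd, which inhibits coagulation, and they rose by 0.82, 0.91 and 1.11. Fibroblast, adipocyte and endothelial markers were higher in the same pools, with medians of 1.11, 1.23 and 0.57, and stromal cells are known to make several members of this list. Acute phase and secreted defence genes were lower: 10 of 18 fell and 2 rose, with a median of -0.85 (adjusted p = 2.31e-09, and adjusted p = 0.387 with an estimated correlation), a list written with some members already seen, as was the list of complement and coagulation genes. Slpi, Saa2 and Fgb fell by 1.63, 1.23 and 1.51, while the polymeric immunoglobulin receptor gene Pigr rose by 1.01 and Hp by 0.76.

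Clock output genes in phase with Dbp had a median of -0.37 (3 of 9 fell and 0 rose, adjusted p = 0.00105, and adjusted p = 0.387 with an estimated correlation), with Tef at -0.85 and Per2 at -0.88. Nr1d1 and Bhlhe41, at 0.06 and 0.13, did not pass and went opposite ways in the 2 sets. Dbp itself is not in the list, and its leading and other tested probe set were at -1.625 and -1.274. The 4 clock genes of opposite phase had a median of 0.04 and 0 passed (adjusted p = 0.633). Of 11 glucocorticoid-induced genes 4 fell and 1 rose (median -0.17, adjusted p = 0.0145, and adjusted p = 0.387 with an estimated correlation), among them the metallothionein genes Mt1 and Mt2, which fell by 0.64 and 0.61. Of 19 ribosomal protein genes and 27 genes of oxidative phosphorylation 0 passed, with medians of -0.01 and 0.07 (adjusted p = 0.497 and 0.255).

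Fibroblast markers rose in the null pools by a median of 1.11. A lower share of tumor epithelium could raise the markers of every other cell type alike. The fibroblast median, however, lay 1.03 above the macrophage median (permutation test over list members, two-sided, p = 1e-05, the smallest that 100000 permutations can give). That p measures the spread among genes, not among pools. It speaks only against an even rise of all other cell types. A lower share of epithelium made up mainly by fibroblast-rich or fat-rich tissue was not tested and stays open. A difference in RNA quality of the kind the Gapdh ratio shows would need the unequal ratios of set 2, yet the median was 1.14 in set 1 alone. The 18S signals were lower in the null pool of set 1, with log2 ratios of -1.43 (5') and -0.70 (3'), and in set 2 the 3' ratio was -0.12 and the 5' signals were within the unspecific level, so a difference in RNA quality of that kind stays open. More fat pad and body wall tissue in the null pools, with adipocyte and skeletal muscle medians of at least 0.64 in each set that had been seen before, and a change in the stroma that goes with the genotype also stay open.

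Genes that fell at least 2-fold lay near each other more often than chance gives: 16 pairs of the 59 genes were within 2 Mb, against a median of 5 in 10000 random draws (permutation p = 8e-04), 8 against 3 within 1 Mb (permutation p = 0.0165) and 20 against 10 within 5 Mb (permutation p = 0.0114), while the 139 genes that rose had 27 pairs against 28 within 2 Mb (permutation p = 0.591). Ctnnd2, Marchf6, Snhg18 and Sdc2 formed one such group and Isoc1, BC023105 and Htr4 another, while Fgb with Fgg and Slpi with Wfdc12 are related genes. In the first 2 groups, the other tested probe sets of Marchf6, Sdc2 and Isoc1 had medians of -0.16, -0.35 and -0.01, and 0 of them were called lower. The pair counts were not rerun without such genes. Loss of a chromosome segment would lower the genes that lie between paired genes. For the 9 of 13 adjacent pairs with tested genes between, the 105 genes from one to the next, the paired ones included, had a median of -0.064 (25th percentile -0.363). That median pools all these stretches, so it speaks against loss of all of them, while loss of a single stretch was not tested and stays open. For the other 4 pairs loss of a segment stays open as well. Of 9 paired genes with further probe sets 33.3% had none that fell 1.5-fold, against 14.3% of 56 genes that rose (Fisher's exact test, two-sided, p = 0.171). Over all 29 lower genes with further probe sets, paired or not, it was 44.8% (Fisher's exact test, two-sided, p = 0.00325), so readings of single probe sets are more frequent among lower genes at large, while for the paired genes sequence differences under single probe sets, shared control of neighbours and changed transcript ends stay open.

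St6gal1 signal was not lower in the null pools. Exchanged labels within 1 set would turn its ratios around, but the ratios of the sets correlated positively across probe sets, at 0.445. With the labels of set 2 exchanged limma called 0 probe sets (103 at an unadjusted p under 0.05), which rests on the same agreement. This speaks against such an exchange only if the shared ratios go with the genotype. A difference in fat pad and body wall tissue, left open above, could also run the same way in both sets, so the exchange is not excluded. Whether the probe sets lie outside the removed part of the gene could not be settled: the log2 ratio of 0.19 is what that would give, but the removed part is not given. Labels exchanged in both sets alike would turn every direction given here and make this ratio -0.19, and no value here tests them, so they stay open. No biological explanation was tested for this pattern.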
